A study of Mus musculus with 2 samples.

How the data were processed

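MicroRNA sequencing was done on left cerebral cortex of B6CASTF1/J mice, the first-generation hybrid of a C57BL/6J and a CAST/EiJ parent, aged 18 to 20 months. The labels give 1 group of 2 biological replicates with 1 technical replicate each, made from total RNA and selected for RNA shorter than 30 nucleotides. The labels disagree on sex: the source name and the sex field say female, while the free-text description says male. Both libraries carry the same donor identifier but different biosample identifiers. Whether they came from separate animals therefore rests on the biological replicate numbers alone, and the spread between the libraries may be technical. No p-value given here measures a spread between animals. No treatment, age or tissue contrast exists, so the values describe 1 tissue and the spread between its 2 libraries.

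The deposited values are read counts per miRNA gene, not normalized by the authors, in 1 table per library. Per the deposited description of the files, the tables use mouse build mm10 and GENCODE release M21. Reads of the CAST parent that differ from that reference may have been lost in placement, which would lower the counts of genes with such variants and was not tested. The aligner and counter, with their settings, are not given in the sources used here. Each table holds 2202 genes and 4 further lines that count unmapped reads, reads with several places in the genome, reads outside features and ambiguous reads. The gene identifiers were tested against the miRNA genes of GENCODE M21 and the sets were identical, so symbols and coordinates were taken from that annotation and all 2202 genes have a symbol. Each table has 3 count columns: without strand, and on each strand. The deposited description names no strand column, so the stranded column with the larger total in both libraries was taken as sense, by a rule fixed before the data were examined. The 4 lines that name no gene were left out of library sizes and tests. They made up 65.2% of the reads in replicate 1 and 65.1% in replicate 2.

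Counting all 4 of those lines and the sense counts, replicate 1 held 14842903 reads, of which 5166667 were sense counts of miRNA genes, and replicate 2 held 12785704 reads with 4459993 sense counts. A count of 0 allows a level of up to 0.581 CPM in replicate 1 and 0.673 CPM in replicate 2, taking 3 counts as the limit. Intervals and limits cover counting error only, since no molecular identifiers are recorded in the sources used here.

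Levels were computed as CPM, the count divided by the sense total of the library and multiplied by 1000000. In the deposited layout the lines for unassigned reads stand apart from the gene counts. A gene was called expressed at 2 CPM or more in both libraries. Means are given with the SD of the 2 libraries. Shares of counts carry exact (Clopper-Pearson) 95% intervals. Concordance was measured across expressed genes on log2(CPM + 1), with a bootstrap of 2000 draws over genes as its error. The biological coefficient of variation was estimated with edgeR 4.0.16 (estimateDisp, intercept only, TMM scaling, filterByExpr). The 50 bootstrap draws over genes used another edgeR estimate of the common value, estimateCommonDisp. With 2 libraries each gene has a single residual degree of freedom, so only the common value is used. Each gene with a pooled count of 20 or more was tested with a two-sided exact binomial test of its pooled count against the TMM-scaled library shares, with Benjamini-Hochberg adjustment at 0.05. This test compares the 2 libraries with each other and not 2 conditions, and its p-values measure counting noise alone. Ratios of replicate 2 to replicate 1 add 0.5 to each count and use TMM-scaled totals. Compared with raw totals, TMM shifted all log2 ratios by 0.13 and DESeq2 1.42.0 size factors shifted them by 0.20. Whether a list stood apart between the libraries is described by the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean expression within 20 ranks on either side.

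The edgeR estimate was tested on simulated counts with the real means and totals. It returned a coefficient of variation of 0.988% for 0% simulated, 20.5% for 20% and 39.6% for 40%. The binomial test of library 2 against library 1 was tested on simulated counts with 200 changed genes, of which those below the pooled-count minimum in the draw were not scored. It recovered 60.9% of 1.5-fold changes, 84.8% of 2-fold changes and 98.4% of 4-fold changes, and called 2 of 248 unchanged genes. These simulated counts held counting noise alone, whereas the spread between the real libraries was 4.11 times that of counting noise. The rates therefore do not carry over to the calls in the real libraries.

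A total of 24 miRNA lists were fixed before the data were examined, by gene symbol. They cover neural cell types, vessels, blood, the meninges and choroid plexus, tissues outside the cortex, imprinted and multicopy clusters, the miR-17 clusters, miRNAs linked to age, and genes whose main mature sequence occurs at several loci. Genes were named by a rule also fixed then: the 20 highest by mean CPM; up to 4 expressed members per list by mean CPM; the 5 with the largest ratio in each direction among genes with a pooled count of 100 or more that passed the binomial test; and up to 5 genes with the most antisense counts among those whose antisense count exceeded the sense count in both libraries. The 3 miR-124 genes were named in addition, after their values were seen. Precursor sequences from the annotation's transcripts were searched for stretches of 20 nucleotides shared with another, non-overlapping miRNA gene on either strand. Such a stretch was present in 1087 of the 2202 genes. Counts are per precursor gene, so the 2 arms of a hairpin cannot be told apart, and other places in the genome were not searched.

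Alternatives tried were other scalings, the unstranded column, other expression thresholds, filters and pseudocounts, leaving out either replicate, and leaving out genes with identical copies. No per-sample column was left unmapped. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.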

Results

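The miRNA content of left cerebral cortex of mice aged 18 to 20 months was profiled in 2 libraries of 5166667 and 4459993 sense counts. Of the 2202 annotated miRNA genes, 409 were expressed at 2 CPM or more in both libraries and 1431 had no sense count in either. The sense counts of miRNA genes made up 34.8% of all reads in replicate 1 and 34.9% in replicate 2. Reads with several places in the genome were more numerous, at 41.8% and 46.4% of all reads, and are listed apart from the gene counts. The median level of expressed genes was 88.9 CPM. Levels are CPM of sense counts, and a list's sum takes all of its measured genes, expressed or not. Values are given as mean ± SD of the 2 libraries (n = 2), unless stated otherwise.

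Genes were ranked by sense counts. Reads with several places are listed apart from these and are not split by gene, so ranks and shares may understate miRNAs with identical copies. By sense counts the most abundant gene was Mir139 (ENSMUSG00000065446.1), which lies in an intron of Pde2a on chromosome 7 at 101475376 to 101475443 (mm10), at 123867 ± 2384 CPM. The let-7 family, broadly expressed miRNAs that are high in differentiated tissue, held the next 3 places. Mirlet7g, in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), reached 106225 ± 36814 CPM. Mirlet7b, within an exon of the non-coding gene Lncppara on chromosome 15 (85707319 to 85707403), reached 69401 ± 3262 CPM. Mirlet7i, within an exon of the pseudogene D630033A02Rik on chromosome 10 (122985640 to 122985724), reached 50272 ± 12115 CPM. Mir127, an imprinted miRNA gene on chromosome 12 (109592846 to 109592915), followed at 49801 ± 14995 CPM, and Mir132, a miRNA induced by neuronal activity on chromosome 11 (75173682 to 75173747), at 38067 ± 6199 CPM. Mir744, in an intron of Map2k4, stood at 37064 ± 2669 CPM and Mirlet7e, in an intron of Spaca6, at 30020 ± 3984 CPM.

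Mir23b (23713 ± 3368 CPM), Mirlet7d (20534 ± 3381 CPM), Mir29a (18699 ± 3113 CPM), Mir125a (18404 ± 13864 CPM), Mir128-1 (17218 ± 4441 CPM) and Mir126a (15834 ± 7669 CPM) came next. The remaining genes of the first 20 were Mir99a, Mir23a, Mir328, Mir652, Mir151 and Mir191, between 15808 CPM for Mir99a and 10008 CPM for Mir191. Mir128-1 shares a stretch of 20 nucleotides or more with Mir128-2, and Mir23a with Mir23b, so their counts are uncertain. Mir139 alone held 12.6% of sense counts in replicate 1 (95% exact interval 12.5% to 12.6%) and 12.2% in replicate 2 (12.2% to 12.2%). The 10 highest genes held 54.9% ± 4.20 and the 20 highest held 69.3% ± 1.31 of sense counts. The order of neighbouring genes was within the spread of the libraries in several places: Mirlet7g was the highest gene in replicate 2 and Mir139 the highest in replicate 1.

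**Figure D1:**
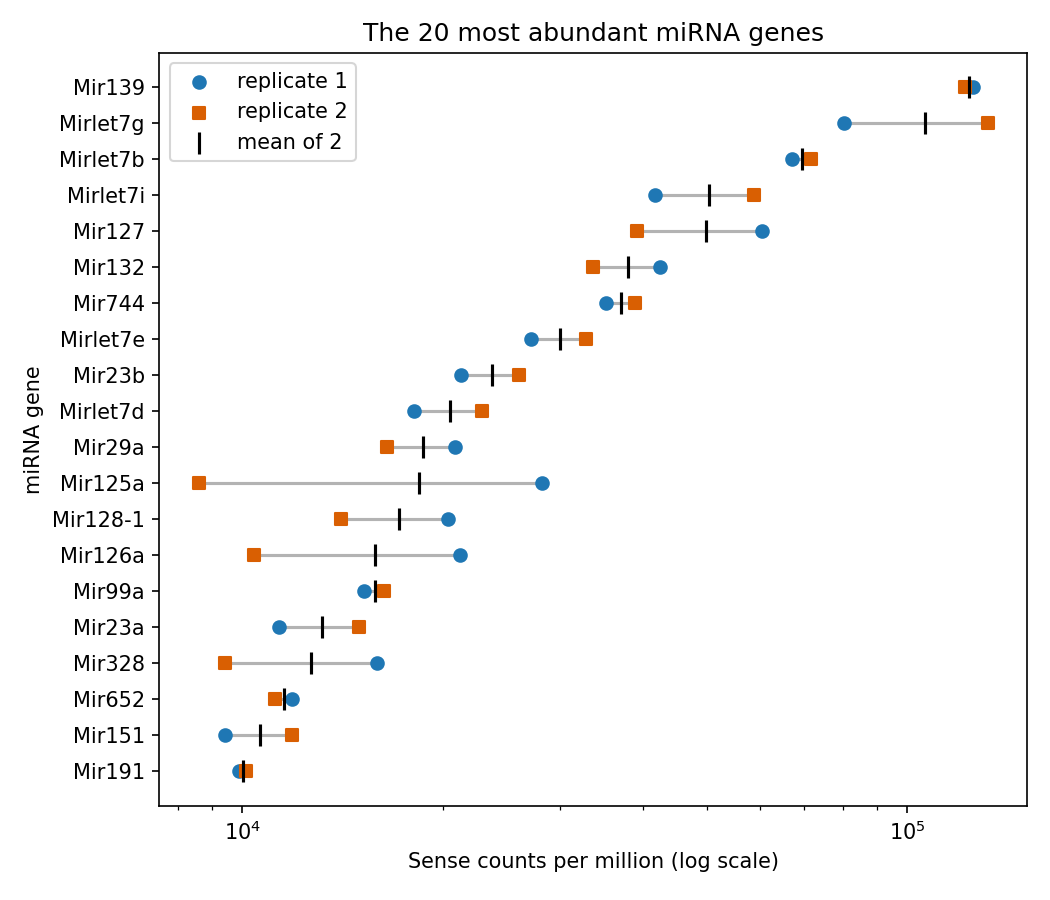
The 20 miRNA genes with the highest mean level. The x axis gives sense CPM on a log scale, circles replicate 1, squares replicate 2 and the black tick their mean; Mir139 and Mir191 differed little between the libraries, while Mir125a was at 28207 CPM in replicate 1 and 8601 CPM in replicate 2.

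Among miRNAs of neural cells, 10 of 14 genes of the neuron list were expressed, summing to 37338 ± 4804 CPM. Mir128-1 was the highest, followed by Mir137 (6618 ± 2001 CPM), a regulator of neuronal maturation, Mir138-1 (4765 ± 295.4 CPM) and Mir138-2 (2978 ± 113.4 CPM). The 3 genes of miR-124, a miRNA of neurons, had few counts. Mir124a-1 had 21 counts in replicate 1 and 6 in replicate 2, Mir124a-2 had 1 and 2, and Mir124a-3 had 2 and 1. The 3 genes of miR-9 summed to 100.2 ± 33.3 CPM, with Mir9-3 at 80.1 ± 31.4 CPM, Mir9-1 at 17.6 ± 1.68 CPM and Mir9-2 at 2.51 ± 0.260 CPM. All 3 copies of each of these miRNAs share stretches of 20 nucleotides or more with each other. All 3 activity-regulated genes were expressed and summed to 39001 ± 6354 CPM, most of it Mir132, with its neighbour Mir212 at 549.7 ± 172.7 CPM and Mir134 at 384.1 ± 17.7 CPM.

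The let-7, miR-125 and miR-99 list was expressed in all of its 18 genes and held 33.6% ± 4.54 of sense counts. The imprinted Dlk1-Dio3 list, whose genes lie on chromosome 12 between 109563692 and 109743795 apart from Mir496b, was expressed in 45 of 50 genes and held 12.2% ± 1.25. After Mir127 its highest members were Mir770 (8405 ± 1316 CPM), Mir433 (7864 ± 1612 CPM) and Mir411 (6859 ± 1245 CPM). In the list named for the Sfmbt2 intron cluster, a multicopy cluster active in placenta, 6 of 68 genes reached the threshold, and the list summed to 809.5 ± 19.4 CPM. Genes were matched to this list by symbol and not by position. It therefore leaves out genes in that intron such as Gm22051 and Gm22072. As 67 of the 68 share a stretch of 20 nucleotides with another miRNA gene, the number expressed is uncertain. Mir467d was the highest of them at 361.6 ± 102.6 CPM, Mir669c followed at 241.4 ± 25.5 CPM and Mir467e at 168.7 ± 49.1 CPM.

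Mir219a-2 (2032 ± 244.9 CPM) and Mir338 (1872 ± 186.3 CPM), which promote oligodendrocyte differentiation, were expressed, while 3 of the 5 genes of the oligodendrocyte list did not reach the threshold. As 4 of these 5, 12 of the 14 neuron genes and 6 of the 9 glia-enriched genes share a stretch with another miRNA gene, the numbers expressed are uncertain. The oligodendrocyte list summed to 3908 ± 62.4 CPM. The glia-enriched list summed to 40228 ± 6834 CPM with 7 of 9 genes expressed, most of it Mir23a and Mir23b. Mir27b stood at 1651 ± 106.3 CPM and Mir21a, induced in reactive glia, at 1447 ± 844.4 CPM. The microglia and leukocyte list summed to 1975 ± 46.9 CPM, led by Mir150 (1220 ± 92.8 CPM) and Mir146 (613.6 ± 81.6 CPM), with Mir142 at 75.5 ± 32.8 CPM and Mir155 at 39.8 ± 14.4 CPM.

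Among vascular and blood miRNAs, Mir126a was the 1 expressed of 2 endothelial genes, at 15834 ± 7669 CPM. The mural cell list summed to 7487 ± 3408 CPM with 2 of 3 genes expressed, with the smooth muscle miRNAs Mir143 at 7008 ± 3030 CPM and Mir145a at 478.7 ± 377.6 CPM. Red cell miRNAs were low, with the erythroid list at 96.8 ± 35.8 CPM with 3 of 4 genes expressed and its member Mir451a at 43.4 ± 5.19 CPM. The list of the choroid plexus and ciliated epithelium summed to 919.3 ± 273.3 CPM with 4 of 7 genes expressed, led by Mir204 (499.8 ± 46.4 CPM) and Mir34c (383.6 ± 312.0 CPM). Of the fibroblast and meninges list 1 of 4 genes was expressed, Mir214 at 78.2 CPM in replicate 1 and 17.3 CPM in replicate 2; 3 of the 4 share a stretch with another miRNA gene, so that number is uncertain.

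Among miRNAs of tissues other than cortex, the striated muscle list was expressed in 2 of 11 genes, at 26.7 CPM in replicate 1 and 78.9 CPM in replicate 2, and 6 of the 11 share a stretch with another miRNA gene, so the number expressed is uncertain. The Hox cluster list was expressed in 2 of 6, at 36.8 CPM and 90.4 CPM, and 2 of the 6 share such a stretch. The liver and gut list summed to 89.0 ± 8.24 CPM with 3 of 4 genes expressed, with the hepatocyte miRNA Mir122 at 57.3 ± 3.90 CPM. The pancreas and endocrine list summed to 285.9 ± 36.4 CPM, and its 1 expressed gene of 5, Mir375, stood at 283.5 ± 38.1 CPM. None of the 14 pluripotent stem cell genes was expressed in both libraries and the list summed to 7 counts in replicate 1 and 13 in replicate 2. The epithelium list, expressed in all of its 7 genes, was at 1555 CPM in replicate 1 and 398.0 CPM in replicate 2. The sensory organ list, expressed in 2 of 3 genes, was at 1007 CPM and 105.2 CPM.

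The miR-17 clusters, linked to proliferation, summed to 8813 ± 4640 CPM with 11 of 16 genes expressed, most of it Mir92b (6561 ± 4427 CPM), which lies on chromosome 3 apart from those clusters. All 8 genes matched to the age-linked list were expressed and summed to 23141 ± 3664 CPM, with Mir34a at 1945 ± 724.2 CPM and Mir29c at 1858 ± 114.4 CPM beside Mir29a. That list also named Mir146a, which matched no annotated symbol and is not in the sum. No young animals were profiled, so these levels are not a change with age. The 58 genes listed by symbol as having identical copies, of which 41 were expressed, summed to 43095 ± 6076 CPM. The symbol rule left out Mir7a, Mir92a, Mir105 and Mir153, which had also been named for this list. A stretch of 20 nucleotides shared with another miRNA gene was found in 57 of the 58. Mir138-1, Mir138-2, Mir219a-2, Mir27b, Mir146, Mir29c, Mir411 and Mir181a-2 also share a stretch with another miRNA gene, and their levels are uncertain for that reason.

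**Figure D2:**
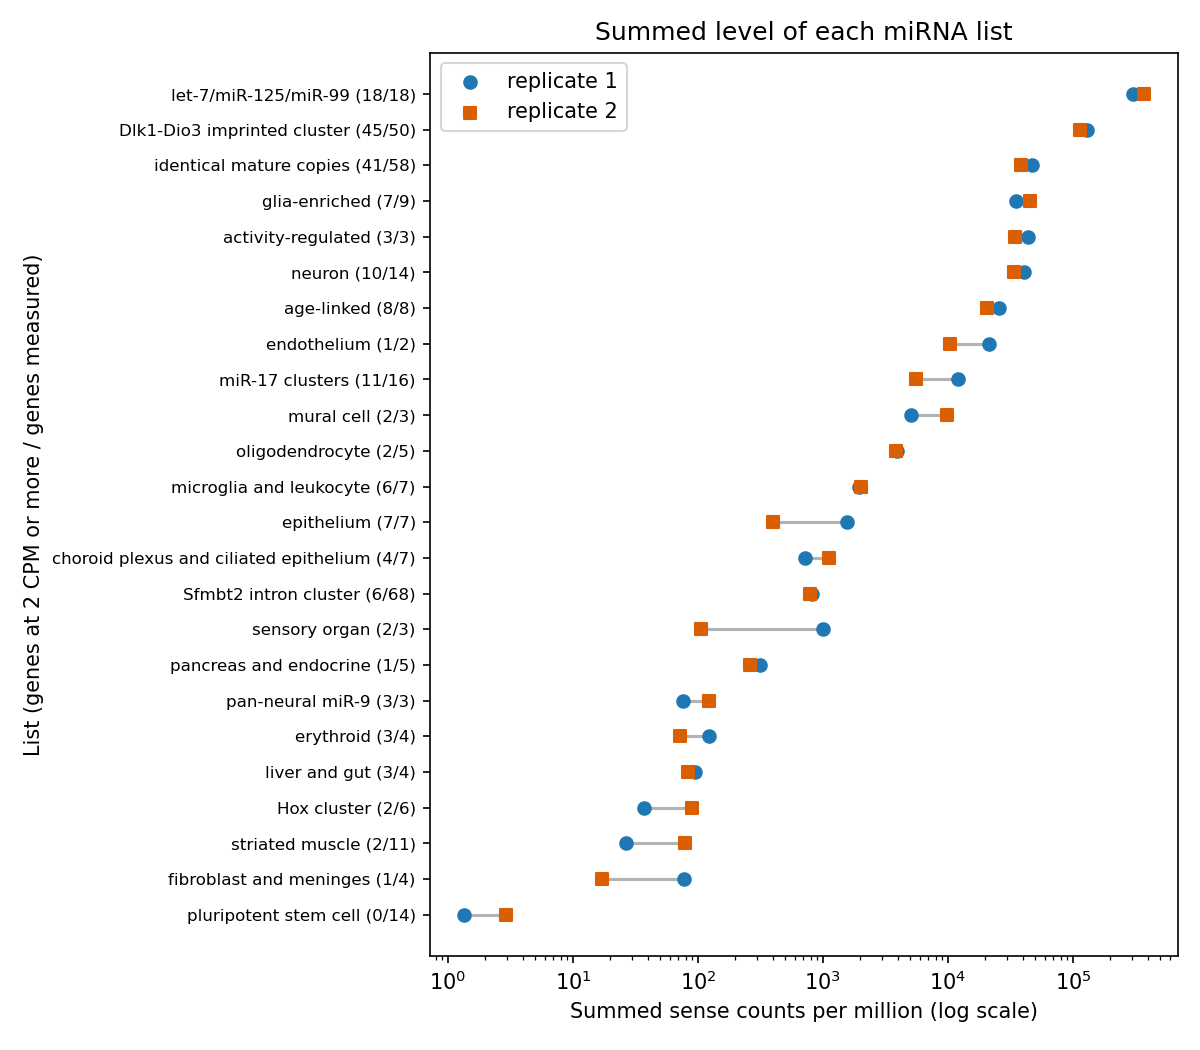
Summed level of each of the 24 miRNA lists. The x axis gives summed sense CPM on a log scale, circles replicate 1 and squares replicate 2, with the expressed and measured genes of each list in brackets; the let-7, miR-125 and miR-99 list has the highest sum in both libraries, and the sensory organ list lies at 1007 CPM in replicate 1 and 105.2 CPM in replicate 2.

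The 2 libraries ranked miRNA genes alike and differed at single genes by more than counting noise. Across the 409 expressed genes, which are not independent replicates, Pearson's r was 0.966 (bootstrap SD 0.0043) and Spearman's rho was 0.960 (bootstrap SD 0.0056). The median absolute log2 ratio was 0.54, and 310 of the 409 genes (75.8%) lay within 2-fold. The edgeR common coefficient of variation was 44.9% (404 genes). A second edgeR estimate (estimateCommonDisp) was 45.2%, with a bootstrap SD of 2.03. That SD treats neighbouring genes as independent and may be too small. A chi-square test of the counts over 512 genes with a pooled count of 10 or more gave 905.0 per degree of freedom, so the libraries differed by more than sampling noise. Separate preparations of the same RNA would do so too, and the libraries are counted as 2 samples because the labels call them biological replicates. The exact binomial test, which knows counting noise alone, called 294 of 438 genes, 143 higher in replicate 2 and 151 higher in replicate 1. Of the 112 that differed over 2-fold, 33 were higher in replicate 2 and 79 in replicate 1. The split depended on the scaling, with 119 higher in replicate 2 and 178 in replicate 1 on total counts, and 155 and 146 with DESeq2 size factors. When the common spread was assumed for every gene in edgeR's exact test of 1 library against the other, 2 genes passed, Mir1247 and Mir200b, both at a Benjamini-Hochberg adjusted p of 0.0130, and 26 had an unadjusted p under 0.05. That spread was estimated from the same libraries and each arm holds 1 library, so these values compare the libraries under an assumption and are no replicated test.

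Of the 5 genes with the largest ratio towards replicate 1, Mir200b and Mir429 are on the epithelium list and Mir183 is on the sensory organ list. Mir1247, in an exon of Dio3os on chromosome 12 (110278048 to 110278129), had 783 counts in replicate 1 and 25 in replicate 2, a TMM-scaled log2 ratio of replicate 2 to 1 of -4.60. Mir200b (-4.37) and Mir429 (-3.23), neighbours on chromosome 4, Mir183 (-3.30) on chromosome 6 and Mir181a-2 (-3.25) followed. In the epithelium list 6 of 7 expressed genes were higher in replicate 1 and Mir203 was higher in replicate 2 (log2 ratio 1.94), and all 7 passed the binomial test, over all genes tested and adjusted over the list alone. Its median log2 ratio of -3.06 was below all of 10000 random lists matched on expression, and both expressed sensory organ genes, with a median of -3.09, lay at percentile 0.765. Random lists drew genes singly, whereas these lists hold neighbours, such as Mir182 and Mir183, Mir200b and Mir429, and Mir141 and Mir200c. These percentiles therefore overstate how many independent genes stand apart.

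Higher in replicate 2 were Mir26a-1, with 45 and 463 counts (log2 ratio 3.69), Mir376c (2.44), Mir140 (2.11), Mir34c (2.02) and the muscle miRNA Mir206 (1.97). Mir26a-1 and Mir376c share sequence with another gene. Mural cell genes were also higher in replicate 2, with a median log2 ratio of 1.49 at percentile 99.4 of matched random lists, but Mir143 and Mir145a are neighbours on chromosome 18 and the same limit applies. The Hox cluster genes Mir10a and Mir10b (median 1.33, percentile 99.5), the microglia and leukocyte list (median 0.67, percentile 99.3) and the choroid plexus list (median 0.86, percentile 98.7) had medians on the same side. Unlike the mural cell genes, the 1 expressed endothelial gene, Mir126a, was higher in replicate 1 (log2 ratio -0.90). In the microglia and leukocyte list 4 of 6 expressed genes passed the binomial test towards replicate 2, its leading gene Mir150 had a log2 ratio of -0.03 and did not pass, and the summed level was 1941 CPM in replicate 1 and 2008 CPM in replicate 2. In the choroid plexus list 2 of 4 passed, the neighbours Mir34b (1.48) and Mir34c on chromosome 9, while its highest gene Mir204 (-0.06) and Mir449a (0.24) did not. Of the lists with 2 or more expressed genes, 20 were compared in this way. The neuron list (median -0.03, percentile 32.4), the oligodendrocyte list (median 0.11, percentile 58.0) and the Dlk1-Dio3 list (median -0.03, percentile 23.9) lay within the central range of random lists.

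**Figure D3:**
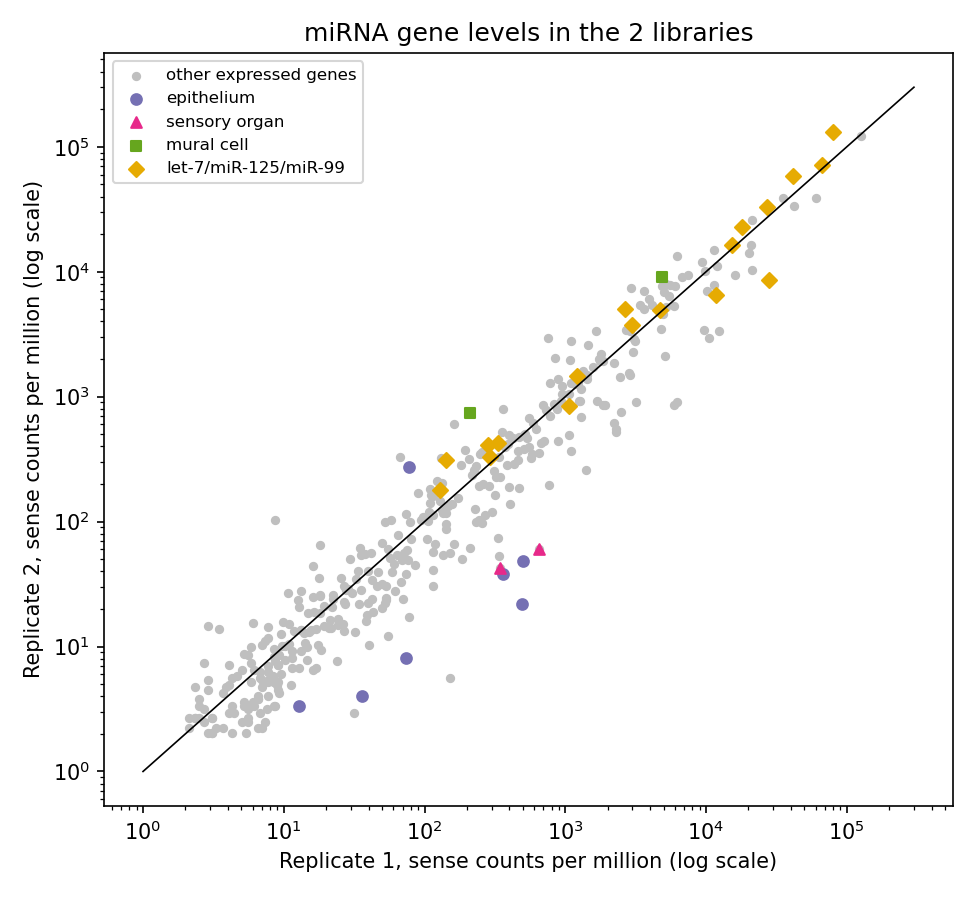
Level of each expressed miRNA gene in replicate 1 (x axis) and replicate 2 (y axis), in sense CPM on log scales, with the line of equal levels. Coloured symbols mark the epithelium, sensory organ and mural cell lists and that of let-7, miR-125 and miR-99; 6 of 7 epithelium genes and both sensory organ genes lie below the line and the mural cell genes above it.

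Antisense counts were 7.08% ± 0.292 of sense plus antisense counts. Of the 405917 antisense counts in replicate 1, 405700 were at the 64 genes that lie opposite another miRNA gene. In replicate 2 these genes held 328968 of 329066. The unstranded column held equal numbers of ambiguous reads, 405700 in replicate 1 and 328968 in replicate 2. The antisense counts at these genes are thus the sense reads of the partner gene counted again, not a separate antisense signal. At the 2138 genes with no such partner the antisense share was 0.00456% in replicate 1 (95% exact interval 0.00397% to 0.00521%) and 0.00237% in replicate 2 (0.00193% to 0.00289%). Antisense exceeded sense counts in both libraries at 28 genes. Gm25927, opposite Mirlet7e, had the most, with 140549 antisense counts in replicate 1, equal to the sense count of Mirlet7e. Mir126b, opposite Mir126a, Gm24083, opposite Mir191, Mir30f, opposite Mir30e, and Gm25301, opposite Mir378a, followed, all with no sense count. In the unstranded column, all 26 expressed genes with an opposite partner, Mirlet7e and Mir126a among them, lost over 90% of their counts. The loss came to 7.85% of sense counts in replicate 1 and 7.38% in replicate 2.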

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

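The tests in this part were chosen after the results were seen. Signal outside the sense counts stood above the limit of 3 counts in both libraries. Reads with several places in the genome numbered 6203588 in replicate 1 and 5928954 in replicate 2, and uniquely placed reads outside miRNA genes numbered 863893 and 573340. Antisense counts at genes with no opposite miRNA gene were 217 and 98. Mir5620, with 62 and 21 antisense counts against 47 and 23 sense counts, and Mir3083, with 47 and 32, held most of these and were named after their values were seen.

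In 17 clusters that hold miRNA genes with and without identical copies, the copies lay below the partners without copies in 15, such as Mirlet7c-2 (1334 CPM) beside Mirlet7b (69401 CPM) and Mir29b-1 (58.9 CPM) beside Mir29a (18699 CPM). The median log2 difference was -1.63, which was not itself tested. It is the value of the Mir106a cluster, where Mir19b-2 had 0 CPM and its partners a mean of 2.96 CPM. Differences ran from -8.29 for Mir29b-1 to 5.78 for Mir26a-2. The mean log2 difference was -2.64 (two-sided sign-flip permutation test of the mean, p = 0.0063). The partners' median of 176.8 CPM argues against low transcription of the shared loci as a general cause, but it stays open where partners were low, as for Mir3078 (4.91 CPM) beside Mir124a-1, the Mir106a cluster (2.96 CPM), Mir215 (0.0968 CPM) and Mir546 (0 CPM); Mir194-2 and Mir26a-2 lay above their partners. A candidate explanation with which the -1.63 and the mean of -2.64 go is that reads fitting several genes were left out of the counts. The -1.63 by itself is weak support, as it comes from a cluster with low levels. Clustered miRNAs can also differ in processing and stability, which was not tested. For miR-124, whose 3 genes summed to 3.33 CPM, low expression and left-out reads cannot be told apart, because the reads with several places are not split by gene.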

How the results depend on the processing

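The alternatives below were chosen before the data were examined. Scaling by TMM or DESeq2 size factors moved no list level and none of the 20 most abundant genes by more than the SD of the libraries. The number of expressed genes stayed within 1.5 times under all alternatives run. No paired analysis was possible because there is 1 group. The cause of the shifts below was not tested unless given.

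With the unstranded column, in which genes opposite another miRNA gene lose their counts, the median level of expressed genes was 60.8 CPM against 88.9 CPM, the top gene's share 13.4% and the share of the top 20 genes 72.0%; of the 20 most abundant genes 8 moved, of which Mirlet7e, Mir126a and Mir191 fell and 5 rose over the smaller total. Leaving out each replicate gave median levels of 60.99 to 94.6 CPM, top-gene shares of 12.6% to 13.2% and top-20 shares of 68.9% to 70.7%. Without a filter r was 0.979 and rho 0.925, and with a filter at 10 CPM 0.954 and 0.947. The coefficient of variation without a filter was 47.4%. The edgeR exact test with the common spread called 2 of 404 genes, against 294 of 438 in the binomial test; the assumed spread, the test and the filter all differ, and their shares in the drop were not tested.

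Taking Mir139 out of the denominator raises all levels by construction. The lists moved by more than their SD were neuron (42624 CPM), let-7, miR-125 and miR-99 (382964), oligodendrocyte (4460), microglia and leukocyte (2254), liver and gut (101.6), pancreas and endocrine (326.3), Dlk1-Dio3 (139178), Sfmbt2 (923.9) and identical copies (49198). Without genes that have identical copies, the neuron list fell to 6851 CPM, miR-9 to 0, oligodendrocyte to 1872 and liver and gut to 68.6, since members were removed. Without Gm25927 the antisense share was 4.41%.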

Other observations

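The tests of counting noise, of another tissue, and of GC content for the epithelial and sensory genes, were chosen after the results were seen, as was the repeat of the cell-type test with 1 value per cluster; the tests of GC content over all genes, cell-type lists and clusters were chosen before theirs.

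Neighbouring miRNA genes differed together between the libraries. Over 40 clusters of 139 genes on the same strand within 10 kb, clusters held 0.611 of the variance of the log2 ratio, against a median of 0.279 for random sets (permutation p = 1e-05, the smallest possible; adjusted over 6 tests 3e-05), and 0.783 against 0.396 without the chromosome 12 cluster. The clusters held 0.423 of the variance of the log2 level against 0.281 (permutation p = 0.0062, adjusted 0.0124), and 0.571 against 0.398 without the chromosome 12 cluster (permutation p = 0.0111, adjusted 0.0167). Genes of a cluster are therefore not independent observations of a difference between the libraries.

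The spread between the libraries was 4.11 times that of counting noise, which describes the pattern and is no separate test of it. A straight line on precursor GC content explained 0.0767 of the variance of the log2 ratio over 316 genes (upper 95% bootstrap bound 0.146). This argues against a straight-line effect of precursor GC content as the main cause. A trend of -0.31 log2 per 10% GC was nevertheless present (permutation p = 1e-05, the smallest possible). The libraries were selected for short RNA, so a read covers only part of a precursor. GC content of the sequenced part was not tested, and an effect of it stays open. Cell-type lists held 0.415 of the variance (permutation p = 0.0282, adjusted 0.0338), which met what had been written down for a different share of cell types in the pieces of tissue. With 1 value per cluster the share was 0.335 (permutation p = 0.218), so that explanation may hold but stays open. With 1 group, no explanation that needs a contrast of treatment, age or tissue could be tested.

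The epithelial miR-200 genes and the sensory organ genes Mir182 and Mir183 were higher in replicate 1, with Mir200b at 493.7 CPM against 21.7 CPM and Mir183 at 653.6 CPM against 60.5 CPM. Counting noise is argued against by the binomial test adjusted over all 438 genes; that all 9 expressed genes of both lists, Mir203 in the opposite direction, lay over 2 counting errors from 0 (largest error 0.413 log2) restates it and is no separate test. The median log2 ratio of the 9 genes was -2.86 once the straight-line GC trend was removed. Their precursor GC content was 45.7% to 55.1% and the trend was -0.31 log2 per 10% GC, so its removal could shift them only little. The measured trend is thus too small to account for their ratios. That outcome was fixed by the slope, and no other effect of GC content, such as that of the sequenced part, was tested. Another tissue or region in the piece of replicate 1 may account for the epithelium list's median of -3.06, but this and a change within cortical cells cannot be told apart without other markers. Squamous epithelium and endocrine tissue were also tried, on 1 gene each, and exclude nothing by themselves: Mir203 had a log2 ratio of 1.94, opposite to the others, and Mir375 of -0.15. Mir205, on the epithelium list with Mir203, had 66 counts in replicate 1 and 15 in replicate 2. Its log2 ratio of -1.76 went with the other genes and not with Mir203.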
